A study of Mus musculus with 8 samples.

How the data were processed

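Olfactory bulbs were dissected from mice carrying a reporter at the neurotensin locus, in which the Nts gene also drives a fusion of tau and green fluorescent protein (GFP). Cells were dissociated with papain and sorted by fluorescence into GFP-positive and GFP-negative populations at embryonic days 13, 15 and 17 (E13, E15, E17) and on the day of birth (P0), and RNA was sequenced from single-end libraries, per the labels' protocols. There were 8 libraries, 1 for each age and population. The source field of all 8 samples reads GFP-positive, so the population was taken from the titles and the cell population field. How many embryos went into each sort is not given in the sources used here.

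The deposited values are FPKM (fragments per kilobase of transcript, scaled to library size) per gene, and the authors' table has 42084 rows. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.9, Cufflinks 2.2.1 and the mouse build mm10 were used; the annotation, strand setting and read filters are not given in the sources used here. The authors set 14 further rows apart because the FPKM estimate failed or the locus held too many reads, and these were not tested. Of the rows, 18292 were at 0 in all 8 libraries and 905 named several overlapping genes, whose reads cannot be told apart. Overlapping, antisense and near-identical genes, such as the hemoglobin pairs, are uncertain for the same reason. Gene positions were taken from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, to which 37334 rows were matched by symbol.

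Read totals are not part of an FPKM table, so depth was read from low values. In 6787 genes with 1 transcript, values were compared with whole multiples of what 1 read is worth after subtracting 200 bases from the transcript length. Between 83.7% and 87.6% of low genes were whole within 0.1 read (values spread evenly would give 20%). The scale was set from the most common value among these same genes, which makes genes at 1 read whole by construction. The share is thus not an independent check of the depth. The implied scale lay between 5500000 and 9470000 reads per library, and an FPKM of 1 on a 2 kb transcript stood for at most 18.9 reads. The scale is relative, because the deposited values may carry a scaling between libraries.

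Values were analysed as log2(FPKM + 1), so fold changes of low genes are understated. Rows with a mean FPKM of at least 1 over the 8 libraries were kept, which left 15149. limma 3.58.1 in R 4.3.3 was used with a mean-variance trend, 2-sided moderated tests and Benjamini-Hochberg adjustment over all kept rows, at a threshold of 0.05. The population difference had age as a block and 3 residual degrees of freedom, so the disagreement between ages is the error. Trends were straight lines over the age order in each population, with 4 residual degrees of freedom. Differences at a single age have no replicate and no test. Nothing in the labels says that libraries of different ages share animals, and p-values measure the departure of single libraries from the model.

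Before the data were examined, 30 gene lists of cell types and functions were fixed, to be tested with camera on the population difference, the GFP-positive trend and the difference of trends, with a preset correlation of 0.01 between genes and again with an estimated correlation. With an estimated correlation the test rests on the 3 or 4 residual degrees of freedom of the fit. It thus has little power, and a list that does not pass it may still differ. The list test on the GFP-negative trend was added after the data were seen. The named genes were fixed by rule too: Nts and Mapt, the 12 largest population differences each way with the same sign at all 4 ages, the largest trends past the threshold, the trend differences with the smallest p, 4 members of each list, and the 3 largest ratios each way at each age. Predicted and clone-named genes, rows naming several genes, mitochondrial genes, Y-linked genes and Xist were not named under that rule except among list members. Other genes are said to be chosen after their values were seen. Some genes that the rule takes are not reported here. The fits were tested on simulated data in which 200 of 15149 genes changed. The population fit recovered 0% of changes of 1 log2 unit, 61.5% of changes of 2 and 84.5% of changes of 3, and the GFP-positive trend fit recovered 0%, 13% and 45.5% of changes of the same size. For the trend this size is the whole change from E13 to P0, not the slope per age step. Changed genes were drawn from rows above a minimum mean level, with noise from the population fit, so recovery in the real data can differ.

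Alternatives covered the pseudocount, the filter, scaling by median-of-ratios factors (0.969 to 1.04), quantile normalization, the variance model, the coding of age and leaving out each age. Leaving out an age leaves fewer residual degrees of freedom. Without E13 or P0 the range of ages is also shorter, which widens the error of a slope by design. An alternative restricted to the 10489 kept rows that are single protein-coding genes was added after the data were seen, both with a new fit and with only the adjustment restricted. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.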

Results

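RNA was compared between neurotensin reporter cells and the remaining cells of the mouse olfactory bulb at 4 ages. There were 4 GFP-positive and 4 GFP-negative libraries, 1 of each at E13, E15, E17 and P0, and no replicates within an age. The implied scale was 9470000, 8770000, 6290000 and 7200000 reads in GFP-positive and 6930000, 9030000, 5500000 and 6870000 reads in GFP-negative cells, in age order. Folds are on the log2(FPKM + 1) scale with their standard errors (n = 4 age pairs).

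The reporter gene separated the populations in every library. Nts, which encodes the peptide neurotensin (chromosome 10, 102481756 to 102490486, minus strand), was at 1036, 955, 673 and 859 FPKM in GFP-positive cells and at 1.92, 4.54, 5.59 and 4.33 FPKM in GFP-negative cells. Its log2 fold was 7.48 ± 0.30 (SE, limma adjusted p = 0.00258). Mapt, which encodes tau (chromosome 11, 104231390 to 104332090), was at 274, 416, 504 and 379 FPKM in GFP-positive and 38.7, 65.7, 75.5 and 120 FPKM in GFP-negative cells, with a log2 fold of 2.45 ± 0.23 (SE, limma adjusted p = 0.0103). The reporter itself encodes tau, and its reads cannot be told apart from those of Mapt in these values.

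Of 15149 rows, 856 differed between the populations, 471 higher and 385 lower in GFP-positive cells, all with the same sign at all 4 ages (limma, adjusted p below the threshold). The test favours such rows, since disagreement between ages is its error. Of all tested rows 4893 (32.3%) had the same sign at all 4 ages. Leaving out an age left few or no calls, with 73 without E13, 0 without E15, 0 without E17 and 2 without P0 (limma). The log2 fold of Nts then lay between 7.15 and 7.75 (SE 0.20 to 0.40), and it passed without E13 alone (limma adjusted p = 0.0353 to 0.0997). The cells were sorted by the reporter of this gene, so its fold says nothing about how the other calls hold. By gene list, 7 of 18 mitral and tufted cell markers and 8 of 27 synaptic vesicle genes were higher, and 13 of 20 GABAergic interneuron, 14 of 31 cell cycle and 8 of 21 radial glia genes lower, while 0 of 30 gene lists passed camera with an estimated correlation (smallest adjusted p = 0.341 with an estimated correlation). That test rests on 3 residual degrees of freedom and gave cell cycle and axon guidance genes the same adjusted p, so it decides little. Among the highest after Nts were AI593442 (log2 fold 4.36), Epb4.1l4a (4.13), Fblim1 (4.12), Cnih3 (4.07), an auxiliary protein of AMPA receptors, and Lamb1 (4.05), a laminin chain. They were followed by the potassium channel gene Kcnj6 (3.75), Tmem132d (3.71), the GABA receptor gene Gabra5 (3.70) and the bicarbonate transporter gene Slc4a10 (3.66). The largest decreases were in homeobox genes of forebrain interneurons and in hemoglobin genes. Dlx1 had a log2 fold of -5.33, Dlx5 of -5.11, Dlx2 of -4.98, Dlx6 of -4.94 and Meis2 of -4.86, and 1 of the rows of the noncoding Dlx6os1 was listed at 0 in all 4 GFP-positive libraries. Hbb-bs had a log2 fold of -6.24, Hbb-bt of -5.70, Hba-a1 of -5.60 and Hba-a2 of -5.28, and Mir1897, a microRNA row, of -4.85.

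**Figure D1:**
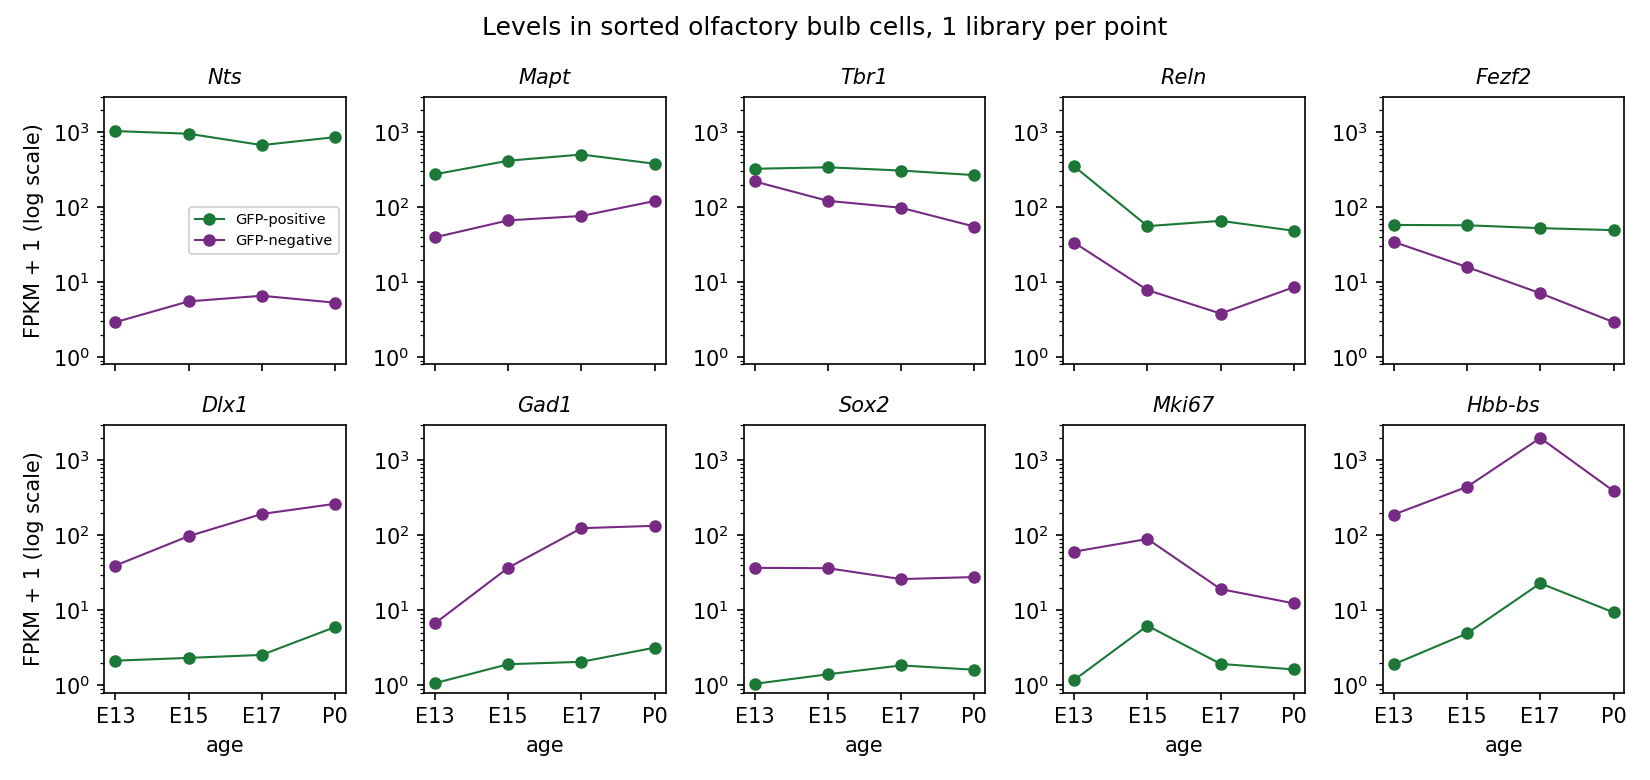
FPKM + 1 on a log axis against age for 10 genes in GFP-positive and GFP-negative cells, 1 library per point. Nts lies between 673 and 1036 FPKM in GFP-positive cells and at or below 5.59 FPKM in GFP-negative cells.

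Of 18 tested mitral and tufted cell markers, genes of the bulb's projection neurons, 7 were higher and 0 lower in GFP-positive cells, or 12 higher and 1 lower adjusted over the list alone. Cdhr1 had a log2 fold of 3.29 ± 0.29 (SE), the secreted glycoprotein gene Reln of 3.21, Uchl1 of 1.86 and the vesicular glutamate transporter gene Slc17a6 of 1.60 (limma adjusted p = 0.0478, and 0.0120 to 0.224 over the alternatives). The transcription factor gene Tbr1 was present in both populations, at 325, 340, 307 and 267 FPKM in GFP-positive and 220, 121, 97.4 and 54.3 FPKM in GFP-negative cells. Of 15 immature neuron and neurite growth genes 8 were higher (11 higher and 1 lower adjusted over the list alone), among them Gap43 (2.39), Nrcam (1.97), Dpysl3 (1.73) and Map1b (1.39). Of 27 synaptic vesicle and release genes 8 were higher (17 higher and 1 lower adjusted over the list alone), among them Sv2b (3.34) and Pclo (1.59). Of 15 neuronal maturation genes 3 were higher (7 higher and 1 lower adjusted over the list alone), Mapt, Syt1 (2.26) and Ina (1.90). Of 34 voltage-gated channel genes 5 were higher and 1 lower (16 and 2 adjusted over the list alone), with Cacna1e at 3.05 and Kcnd3 at -1.59. Of 11 GABA receptor genes 3 were higher (4 adjusted over the list alone), among them Gabra5 and Gabra3. Of 10 neuropeptide genes 3 were higher (5 higher and 1 lower adjusted over the list alone), Nts, Scg2 (2.84) and Tac1 (2.43). The sort fixed the outcome for Nts, and without it 2 of 9 were higher and the list did not pass (camera adjusted p = 0.150 with the preset correlation). Without E13, E15, E17 and P0 in turn, the members higher, adjusted over the list alone, were 10, 9, 5 and 16 for synaptic vesicle genes, 2, 3, 2 and 6 for neuronal maturation genes and 8, 3, 3 and 8 for voltage-gated channel genes.

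Of 20 GABAergic interneuron genes 13 were lower and 1 higher in GFP-positive cells (17 and 1 adjusted over the list alone). Gad1, which encodes a GABA-synthesizing enzyme, had a log2 fold of -4.56, and the member that was higher, Calb2, of 2.04. Of 31 cell cycle genes 14 were lower (30 adjusted over the list alone), among them Top2a (-4.43), Ube2c (-4.17), Mki67 (-3.94) and Ccna2 (-3.68). The median of these genes in GFP-positive cells was 3.74 FPKM at E15 and 0.483, 1.40 and 1.64 FPKM at E13, E17 and P0. Of 21 radial glia and progenitor genes 8 were lower (18 adjusted over the list alone), among them the transcription factor genes Sox1 (-4.71), Pax6 (-4.69) and Sox2 (-4.44). Of 16 proneural genes 3 were lower (10 adjusted over the list alone), among them Mfng (-3.82) and Sstr2 (-3.28). Of 12 astrocyte genes 5 were lower (8 lower and 1 higher adjusted over the list alone), with Slc1a3 at -4.23 and Mlc1 at -2.78. Of 17 Wnt pathway genes 6 were lower (8 adjusted over the list alone), among them Tcf7l2 (-3.36), Fzd8 (-3.26) and Sfrp1 (-3.04). Of 6 erythroid genes 4 were lower (6 adjusted over the list alone). Without E13, E15, E17 and P0 in turn, the members lower, adjusted over the list alone, were 12, 6, 12 and 14 for radial glia genes, 10, 3, 4 and 10 for proneural genes and 8, 5, 7 and 7 for Wnt pathway genes. The GFP-negative libraries held more red cell transcripts at each age, with Hbb-bs at 189, 444, 1994 and 391 FPKM against 0.911, 3.93, 21.9 and 8.41 FPKM.

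**Figure D2:**
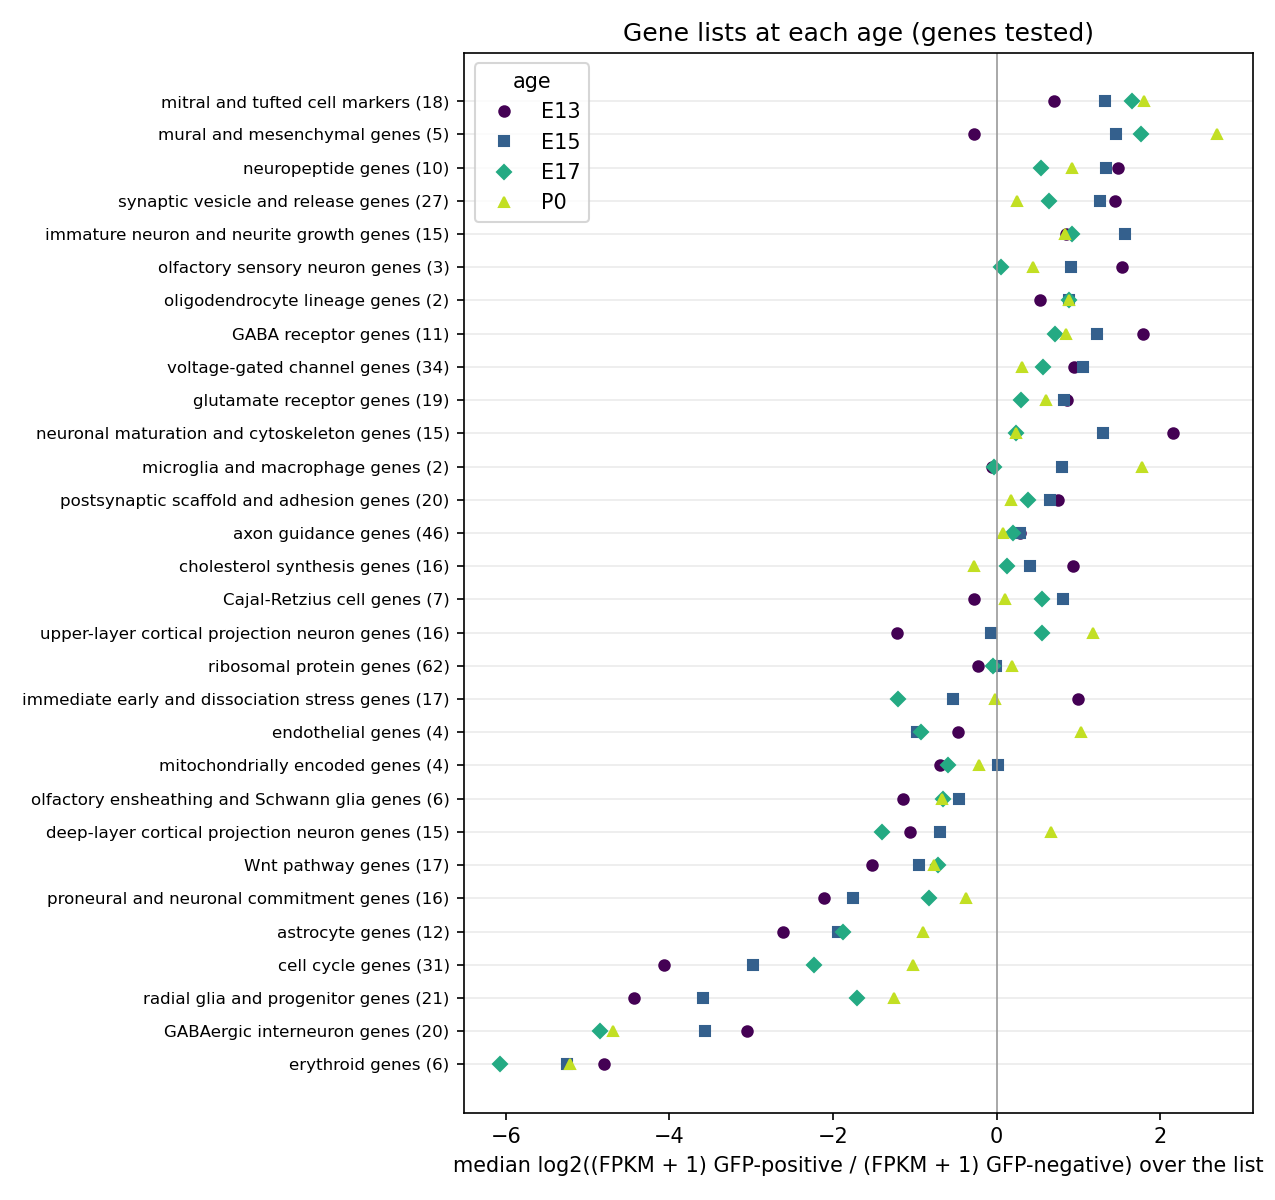
Median log2 ratio of GFP-positive to GFP-negative cells over each gene list (FPKM + 1), 1 point per age, with the number of genes tested in parentheses. GABAergic interneuron genes, with a median log2 fold of -4.20 over the 4 ages, lie far below 0.

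With camera and the preset correlation, 18 of 30 lists differed, 10 higher and 8 lower, or 17 with Nts and Mapt left out of the lists. Beyond those above they were glutamate receptor genes (median 0.73), postsynaptic genes (0.45) and cholesterol synthesis genes (0.29), which were higher, and olfactory ensheathing and Schwann glia genes (-0.60), which were lower. With an estimated correlation 0 of 30 lists passed. Of 19 glutamate receptor genes 1 was higher and 2 were lower, Grik3 (-2.73) and Gria1 (-1.73), or 7 and 2 adjusted over the list alone, which became 3 and 2 without E13, 0 and 2 without E15, 6 and 2 without E17 and 0 and 1 without P0. Of 20 postsynaptic genes 0 were higher and 1 lower, Nlgn1 (-1.42), with the same counts adjusted over the list alone (limma), and 0 each way with any 1 age left out. Of 16 cholesterol synthesis genes 0 passed per gene either way (limma, 3 at unadjusted p under 0.05). Of 6 ensheathing glia genes 1 was lower, Ednrb (-3.13).

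Lists that did not pass camera included 15 deep-layer cortical genes, whose members split. Bcl11b (1.41) and Tbr1 (1.49) were higher, while Foxp2 (-3.08), Sox5 (-2.85), Nr4a2 (-2.43), Nfia (-1.93) and Nfib (-1.75) were lower, and 2 members passed as higher and 5 as lower. Axon guidance genes also split, with 9 of 46 higher and 3 lower, among them Unc5a (2.51) and Cntn2 (2.36) and, lower, Plxna4 (-3.40). Upper-layer cortical genes had 2 higher of 16, Epha3 (2.72) and Mdga1 (2.52). Oligodendrocyte, mural, olfactory sensory neuron, mitochondrially encoded, immediate early and dissociation stress, microglia, Cajal-Retzius, endothelial and ribosomal protein genes did not pass either. Only 2 of 13 oligodendrocyte, 2 of 18 microglia, 3 of 16 olfactory sensory neuron, 4 of 18 endothelial and 5 of 16 mural genes were kept and tested. For these cell types the result says little. For ribosomal protein genes the median log2 fold was -0.03 and the test pointed the other way (camera adjusted p = 0.989).

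Restricted to single protein-coding genes, an alternative chosen after the data were seen, the count was 1532 (807 higher), against 870 with the fit of all kept rows and only the adjustment restricted, and it was 297 with no filter.

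Over age, no single gene in GFP-positive cells passed the test, while camera called 10 of 30 lists with the preset correlation, 7 rising, and 0 with an estimated correlation (smallest adjusted p = 0.264 with an estimated correlation). Without E13 it called 5 lists, 2 rising, and without P0 7 lists, 3 rising. limma called 0 of 15149 rows, with 1788 at unadjusted p under 0.05. Upper-layer cortical genes had a median slope of 0.36 log2 units per age step (7 of 16 rose adjusted over the list alone), and Cux1 was at 59.6, 112, 158 and 176 FPKM from E13 to P0. Cholesterol synthesis genes had a median slope of -0.35 (8 of 16 fell adjusted over the list alone), with Hmgcs1 at a slope of -0.50 and Sqle at -0.35. Neuronal maturation genes (median -0.28) and synaptic vesicle genes (-0.15) had negative slopes, with Ina at -0.64, and adjusted over the list alone 3 of 15 maturation genes fell, while 1 of 27 vesicle genes rose and 0 fell. Ribosomal protein genes (0.16), GABAergic interneuron genes (0.24), radial glia genes (0.08), ensheathing glia genes (0.39), endothelial genes (0.42) and mural genes (0.85) had positive slopes. Rgs5, a pericyte gene, was at 0.108, 27.4, 24.4 and 86.2 FPKM, and Pdgfrb at 0, 2.83, 1.09 and 6.61 FPKM. Without E13, E15, E17 and P0 in turn, adjusted over the list alone, 0, 6, 3 and 0 upper-layer genes and 0, 1, 0 and 0 vesicle genes rose, and 0, 0, 4 and 0 cholesterol synthesis genes and 0, 6, 0 and 0 maturation genes fell (2 rose without E15).

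Genes chosen after their values were seen included Nrgn, at 0.431, 1.18, 10.3 and 31.8 FPKM, and Cdh4, at 22.3, 30.3, 67.0 and 140 FPKM. Cntnap2 was at 249, 87.8, 58.3 and 31.4 FPKM, and Gap43 at 634, 363, 238 and 117 FPKM. None of these slopes passed over all kept rows (limma adjusted p = 0.271 for each). Among single protein-coding genes, fitted anew, 4 passed, Cdh4 (slope 0.89), Nrgn (1.59), Pnrc1 (0.74) and Cntnap2 (-0.94), each at limma adjusted p = 0.0475. The count was 0 with the fit of all kept rows and only the adjustment restricted to these genes. E13 set against the 3 later ages gave 63 calls, and 52 of the 58 rows with a known length were under 200 bases.

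In GFP-negative cells, genes of dividing and progenitor cells had negative slopes over age and interneuron genes positive ones. Camera called 14 of 30 lists with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.0905 with an estimated correlation). Cell cycle genes had a median slope of -0.85 per age step (23 of 31 fell adjusted over the list alone), radial glia genes of -0.73 (11 of 21 fell), proneural genes of -0.64 (9 of 16 fell) and mitral and tufted cell markers of -0.55 (7 of 18 fell). GABAergic interneuron genes had a median slope of 0.77 (15 of 20 rose adjusted over the list alone), with Gad1 at 5.72, 36.0, 124 and 133 FPKM and Dlx1 at 38.6, 96.7, 192 and 263 FPKM. Per gene, limma called 1 of 15149 rows, with 2507 at unadjusted p under 0.05. That gene was Fezf2, a transcription factor gene, at 33.4, 14.9, 6.12 and 1.93 FPKM, with a slope of -1.18 (limma adjusted p = 0.0488). Without E13, E15, E17 and P0 in turn, adjusted over the list alone, 18, 21, 6 and 0 cell cycle, 3, 7, 5 and 1 proneural and 6, 8, 7 and 1 mitral and tufted genes fell, and 0, 14, 14 and 9 GABAergic genes rose.

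Wnt pathway (-0.32), upper-layer cortical (-0.26) and astrocyte genes (-0.47) also had negative slopes. Voltage-gated channel (0.21), synaptic vesicle (0.19), glutamate receptor (0.38), postsynaptic (0.29), GABA receptor (0.25) and immediate early genes (0.47) had positive slopes. Fezf2 did not pass when any age was left out. With a new fit of single protein-coding genes, an alternative chosen after the data were seen, 408 passed, 135 rising and 273 falling. The count was 1 with the fit of all kept rows and only the adjustment restricted to these genes.

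**Figure D3:**
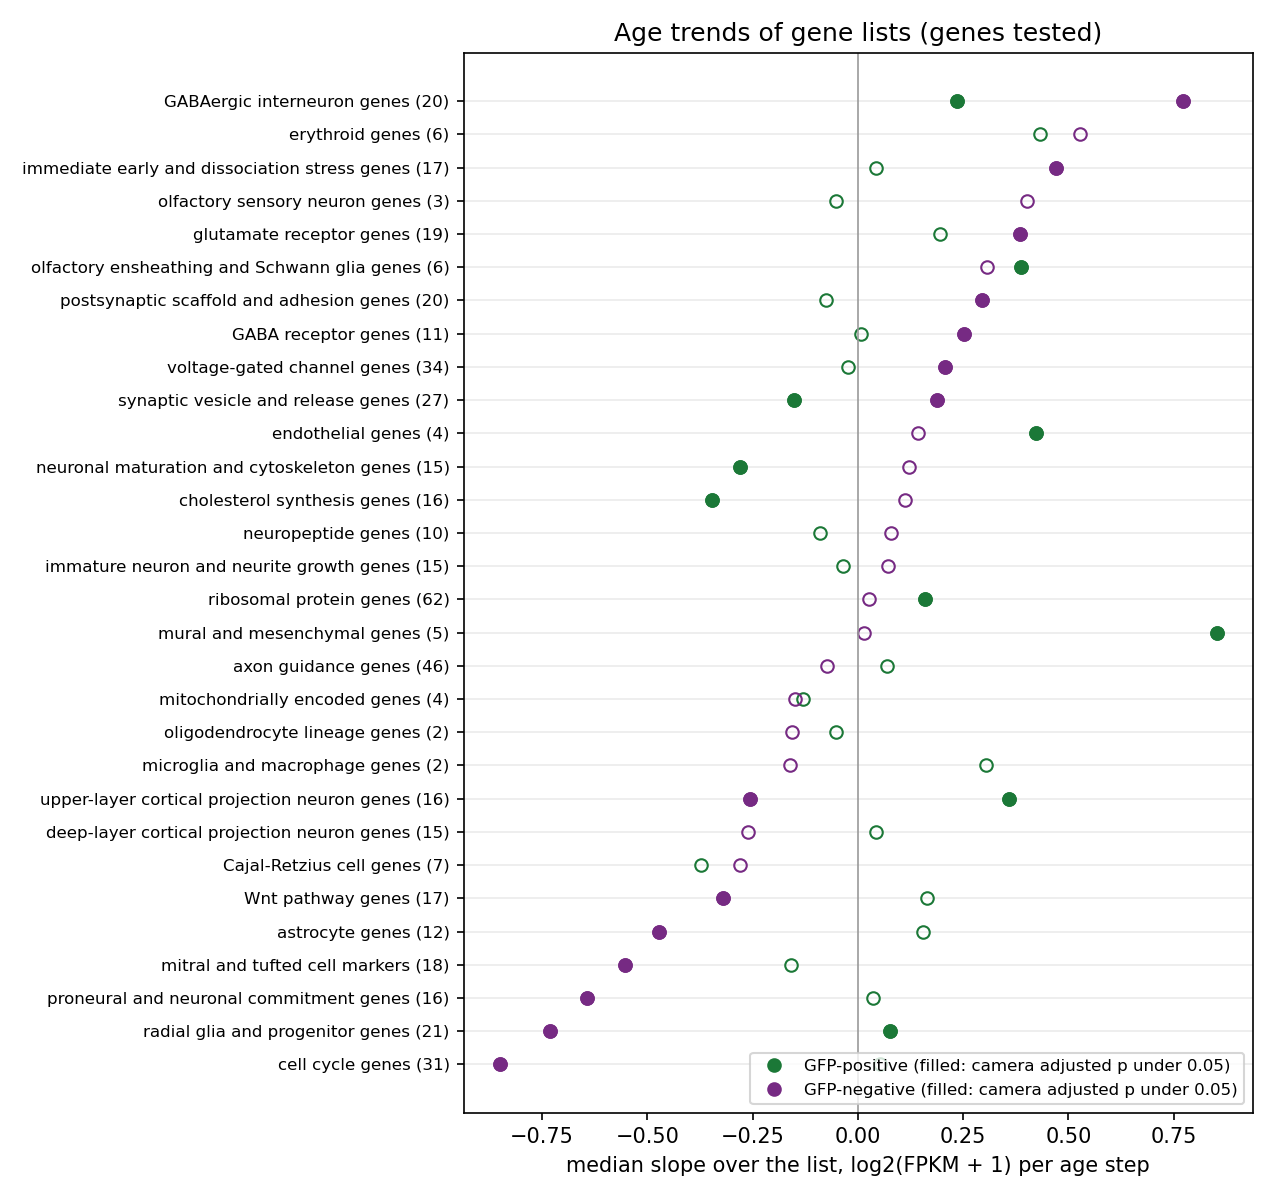
Median slope of log2(FPKM + 1) per age step over each gene list in GFP-positive and GFP-negative cells, filled where camera with the preset correlation passed. Cell cycle genes lie at -0.85 in GFP-negative and 0.05 in GFP-positive cells.

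The age trends differed between the populations by the list test with the preset correlation, which called 16 of 30 lists, and not per gene. With an estimated correlation 0 of 30 lists passed (smallest adjusted p = 0.176 with an estimated correlation). Radial glia genes (difference of slopes 1.08, GFP-positive minus GFP-negative), cell cycle genes (0.82), upper-layer cortical genes (0.80) and proneural genes (0.45) had the higher slope in GFP-positive cells, and GABAergic interneuron genes (-0.45), synaptic vesicle genes (-0.34) and neuronal maturation genes (-0.37) the lower. In GFP-positive cells the list median was 0.695, 2.52, 1.25 and 2.32 FPKM for radial glia genes and at most 3.74 FPKM for cell cycle genes. Such low levels leave little room for a fall. Median slopes of these lists were 0.08 and 0.05 in GFP-positive and -0.73 and -0.85 in GFP-negative cells. Their differences of slopes thus lay mainly in the fall in GFP-negative cells. limma called 0 of 15149 rows, with 1593 at unadjusted p under 0.05. Adjusted over the list alone, 15 of 21 radial glia, 5 of 31 cell cycle, 9 of 16 upper-layer, 4 of 16 proneural, 5 of 20 GABAergic, 2 of 27 synaptic vesicle and 6 of 15 neuronal maturation genes passed. Without E13, E15, E17 and P0 in turn these were 2, 10, 7 and 0 radial glia, 0, 1, 0 and 0 cell cycle, 0, 8, 8 and 2 upper-layer, 0, 1, 0 and 0 proneural, 0 GABAergic each time, 0, 3, 1 and 0 synaptic vesicle and 0, 7, 0 and 0 neuronal maturation genes. The shorter range of ages without E13 or P0 widens the error of a slope by design. Fewer passes there thus do not show that those ages carried the difference. The smallest unadjusted p, none past the adjusted threshold, belonged among higher slopes to Fezf2, Brca1, Cdh4, Snora23, Mcm3, Prc1, Tacc3 and Gli3. Among lower slopes they belonged to Spon1, Kcnip1, S100a10, Cdkn1a, Camk2b, Rab3a, Islr2 and Sez6l (limma adjusted p = 0.253 for each of the 16). Gli3, a transcription factor gene of hedgehog signalling, was at 115, 81.0, 12.9 and 5.39 FPKM in GFP-negative and 0.409, 1.84, 2.02 and 2.99 FPKM in GFP-positive cells. Spon1 was at 0.413, 2.36, 12.1 and 30.1 FPKM in GFP-negative and 1.20, 0.591, 0.398 and 0.441 FPKM in GFP-positive cells.

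Among single protein-coding genes, fitted anew, 7 passed, Brca1, Cdh4, Fezf2, Gli3, Mcm3 and Prc1 with the higher and Spon1 with the lower slope in GFP-positive cells (limma adjusted p = 0.0450 for each). The count was 0 with the fit of all kept rows and only the adjustment restricted to these genes.

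At single ages, without a test, 2-fold differences were more numerous at E13 than at P0. At E13, 1668 rows were at least 2-fold higher and 2115 lower in GFP-positive cells, against 1339 and 1545 at E15, 1514 and 1639 at E17 and 1185 and 1064 at P0. Across all 4 ages 226 rows were higher and 200 lower. Ratios were ranked among the rows that could be named under the rule. At E13 Nts had the largest of these ratios higher in GFP-positive cells (log2 ratio 8.47), and Snord14a the largest in size lower there (-9.52). The others of the 3 largest ratios each way at each age among these rows belonged to small RNA rows listed at 0 in 1 of the populations: Mir28b, Mir6921, Mir103-2 and Mir5125 at E13, Snord35a, Mir26a-1, Mir6481, Mir3473d, Snord71 and Mir1933 at E15. At E17 they were Mir6368, Snord72, Snord7, Mir5128, Mir6335 and Snord118, and at P0 Snord71, Mir3098, Mir344-2, Mir378b, Mir544 and Mir3108. On such short rows 1 read is worth a large FPKM.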

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

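Every test in this part was planned. The age trend differed between GFP-positive and GFP-negative cells for 16 gene lists by camera with the preset correlation, and for 0 with an estimated correlation. In these lists the median difference of slopes (GFP-positive minus GFP-negative, log2 per age step) was 1.08 for radial glia, 0.97 for mural and mesenchymal, 0.82 for cell cycle, 0.80 for upper-layer cortical, 0.61 for astrocyte, 0.55 for Wnt pathway, 0.45 for proneural and 0.44 for mitral and tufted cell genes. It was -0.45 for GABAergic interneuron, -0.43 for immediate early and dissociation stress, -0.37 for neuronal maturation, -0.37 for cholesterol synthesis, -0.34 for synaptic vesicle, -0.26 for voltage-gated channel, -0.25 for GABA receptor and -0.21 for postsynaptic genes. Radial glia and cell cycle genes were low in GFP-positive cells at each age (list medians at most 2.52 and 3.74 FPKM). Their differences thus lay mainly in the fall in GFP-negative cells.

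The rows that the authors set apart because the estimate failed held values that no comparison used. The estimate failed in 8 of 8 libraries for Dcx and in 4 of 8 for the row with Zbtb20, so the values below are uncertain. Dcx, which encodes doublecortin of migrating neurons, was at 766, 754, 928 and 1156 FPKM in GFP-positive cells and at 408, 513, 1186 and 1295 FPKM in GFP-negative cells from E13 to P0. Zbtb20, in a row shared with Mir568, was at 3.94, 58.3, 260 and 303 FPKM in GFP-positive cells and at 142, 249, 273 and 575 FPKM in GFP-negative cells.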

How the results depend on the processing

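The restriction to single protein-coding genes, the list tests in GFP-negative cells, median-of-ratios scaling of the lists, the lists without Nts and Mapt and the counts within lists without an age were chosen after seeing the data. The population difference (856 calls) gave 507 with a pseudocount of 5, 297 with no filter, 568 without a variance trend, 1407 with age as a linear term and 1532 among protein-coding genes, and 0 to 73 when an age was left out. Leaving out an age takes away libraries and, without E13 or P0, shortens the range of ages behind a slope. With the fit of all kept rows and only the adjustment restricted to protein-coding genes the count was 870, and the trends gave 0, 1 and 0, so fewer tested rows alone did not give these rises. The new fit leaves each gene's fold and own residual spread unchanged. It differs only in the common spread that the moderated test takes from all fitted rows, so the further rise came from there. For Nts the log2 fold was 7.48 in both, with an SE of 0.298 and, in the new fit, 0.273. For the other alternatives the cause was not tested. The remaining alternatives gave 772 to 1049. The trend in GFP-positive cells (0 calls) gave 4 among protein-coding genes and 63 with E13 against the 3 later ages. The trend in GFP-negative cells (1 call) gave 77 with a pseudocount of 5, 408 among protein-coding genes, 69 with E13 against the later ages, and 0 with quantile normalization, without a variance trend, with P0 set 3 days after E17 and without any 1 age. The difference of trends (0 calls) gave 7 among protein-coding genes and 107 with E13 against the later ages. Of the calls with E13 set apart, 52 in GFP-positive and 50 in GFP-negative cells were on rows under 200 bases, whose cause stays open; it was not tested for the others. Counts of called lists, 18, 10, 14 and 16 in the order of the comparisons, were 0 with an estimated correlation, and for the GFP-positive trend 5 to 9 with an age left out. The test with an estimated correlation rests on 3 or 4 residual degrees of freedom, so those counts of 0 do not show that no list differed. The 2-fold counts with an FPKM of at least 1 in the higher library were 4455 at E15, 4987 at E17 and 3707 at P0, and 4-fold counts were 1571, 1211, 1317 and 987 in age order, by construction. No named gene past a threshold changed sign under any alternative run. For the population difference most of these alternatives could not change it. All calls had the same sign at all 4 ages, and the filter and the variance model leave the fold as it is. Of 92 genes past the threshold for the population difference, 30 no longer passed with no filter, 15 with a pseudocount of 5 and 14 without a variance trend, Slc17a6, Nfia and Slc1a3 with no filter among them, and 92 without E15 or without E17. Adjusted over the list alone, 27, 23, 28 and 30 of 31 cell cycle genes and 16 of 20 GABAergic genes each time were lower in GFP-positive cells without E13, E15, E17 and P0 in turn. An FPKM of 1 on 2 kb stands for at most 18.9 reads, which limits low genes and short rows most.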

Other observations

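Tests on Xist with the Y-linked genes, Xist against the highest nuclear RNA, the cell cycle transcripts and the splits of the libraries were chosen after the result was seen, and the bounds of the Y-linked and cell cycle tests were revised once their values were known; the median of the nuclear RNAs was chosen before its result, and the small RNA test after the E13 calls and earlier tests of them, since dropped, but before the other ages' counts. Genes in the next paragraph were chosen after their values were seen.

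GFP-positive cells also had more Kit, a receptor tyrosine kinase gene (log2 fold 3.42, limma adjusted p = 0.0119), Tshz2 (3.34), the transcription factor gene Tfap2e (3.18), Igfbp5 (3.09), the growth factor gene Igf1 (2.86) and Gcg, the proglucagon gene (2.86, limma adjusted p = 0.0446), higher in 4 of 4 age pairs. Gcg was at 10.2, 56.9, 49.6 and 23.0 FPKM in GFP-positive cells. Reln was at 349 FPKM in GFP-positive cells at E13 and at 55.0, 64.8 and 47.5 FPKM later, and Cdhr1 at 75.4 FPKM at E13 and 6.68, 13.1 and 16.1 FPKM later. Eomes was at 69.3, 149, 161 and 150 FPKM in GFP-positive and 111, 82.8, 34.0 and 17.3 FPKM in GFP-negative cells.

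For the population difference without the age block, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave 1049 calls, and the highest other gave 5. This argues against chance only if all 8 libraries are taken as exchangeable, which leaves the age pairs out of account. The design pairs the libraries by age, so these splits do not exclude chance. With the age block, only 8 splits part every age pair, too few for a share under 0.05; the real one, 1 of the 8, gave 856 calls and the highest other 3. For the trends, 12 orders of the ages can be told apart, also too few; the highest other order gave 0 calls in each population.

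With each age in turn set against the other 3 (limma, 1 library against 3, the spread coming from the 3 and from the other rows), 52, 35, 74 and 56 called rows in GFP-positive and 50, 55, 64 and 57 in GFP-negative cells were under 200 bases, from E13 to P0. Of these, 47, 28, 72 and 51 in GFP-positive and 48, 48, 58 and 52 in GFP-negative cells had reads at that age and were at 0 at the other 3. Such rows pass by their zeros, so these counts cannot tell apart the large worth of 1 read on a short row from expression at 1 age.

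Xist, the noncoding RNA of the inactive X chromosome, stood apart at E17, at 3029 FPKM in GFP-positive and 2669 FPKM in GFP-negative cells against 230 to 1056 FPKM in the other libraries. More female embryos in those pools may be the source, but the summed level of Ddx3y, Eif2s3y, Kdm5d and Uty was 36.5 FPKM in E17 GFP-positive cells, above the 19.4 FPKM at E15, and 26.9 FPKM in GFP-negative cells, the lowest there. E13 GFP-positive cells had a sum near that of E17 (36.2 FPKM) with Xist at 230 FPKM. The populations at E17 point apart, so more female embryos cannot be told apart from other sources. More nuclear RNA in those libraries is argued against as the whole cause, since Xist lay 3.20 log2 units above the mean of the other ages in GFP-positive and 2.27 in GFP-negative cells, against at most 0.82 and 0.72 for 8 other nuclear RNAs (SD 0.42 and 0.66); as a part of it this cannot be told apart, their median being 0.50 and 0.47, between the bounds set beforehand. Age itself stays open, untested.

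Cell cycle transcripts were highest among GFP-positive libraries at E15, with a list median of 3.74 FPKM against 0.483, 1.40 and 1.64 FPKM at E13, E17 and P0. GFP-negative cells carried over in the proportions of their own library are argued against as the whole cause. As a percent of the GFP-negative level at E15, the median was 10.6% for cell cycle genes (quartiles 7.37% to 17.6%) and 2.31% for GABAergic genes (1.38% to 14.5%), a ratio of 4.57 within 1 pair of libraries. Of 18 GABAergic genes 12 lay below 7.37%, with Dlx1 at 1.37%, Dlx5 at 2.08% and Meis2 at 4.03%, although Calb2, Tshz1, Etv1, Pbx3, Zic1 and Slc32a1 lay above it. Among erythroid genes Hbb-bs (0.885%), Hbb-bt (0.347%), Hba-a1 (1.8%) and Hba-a2 (1.82%) lay below 7.37% and Alas2 (29.3%) above it. Dividing cells with the reporter may contribute, but this cannot be told apart from a selective carry-over of dividing cells: radial glia genes were at 6.06%, a ratio of 2.63 to GABAergic genes, and over the same 15 cell cycle genes the percent was 4.15%, 10.9%, 15.1% and 22.3% from E13 to P0, not highest at E15.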
